A study of Rattus norvegicus with 6 samples.

How the data were processed

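Rat C6 glioma cells were treated for 24 h with forskolin (FSK), an activator of adenylyl cyclase that raises cAMP, or with the vehicle DMSO. Bulk RNA sequencing of total RNA was analysed here for 3 FSK libraries and 3 DMSO libraries. The submitters' processing notes list cutadapt, HISAT2, StringTie, edgeR, DESeq2 and the genome build Rnor_6.0, without versions or settings. The deposited table holds whole-number counts and FPKM values, both so named in the file headers, for 32623 genes with 26976 distinct symbols. FPKM is 0.0001 wherever the count is 0. Whether 1 count is a read or a read pair, the strand rule of the counting, and the annotation release are not given in the sources used here. Gene positions are those of the table, on Rnor_6.0. A gene table of a later rat build was used only to match symbols and synonyms, never for positions.

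The counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, the default expression filter, a quasi-likelihood negative binomial fit, and 1 comparison, FSK against DMSO, without a block. Adjusted p-values are Benjamini-Hochberg values from this edgeR quasi-likelihood test over the 14166 genes that passed the filter, and the threshold was an adjusted p of 0.05. Fold changes are log2 values, FSK over DMSO, given ± the standard error taken from the quasi-likelihood F statistic. CPM values (counts scaled by library size and TMM factor) are given as mean ± SD (n = 3). Where a group had 0 counts in all 3 libraries, the fold change is a bound computed with a floor of 3 counts per library.

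The comparison, its test, the other settings, the naming rule and the gene lists were fixed before the data were examined. There were 36 lists of CREB1 targets, cAMP and PKA pathway members, brain cell-type markers, cell-cycle genes, reported miR-221/222 targets, matrix, metabolic, stress, immune and signalling genes. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 36 lists, and again with a correlation estimated from the residuals. The second version also has only the few residual degrees of freedom of 6 libraries, so lists pass it less easily whatever their correlation. Camera compares a list with the other genes. Fry, run as a description, tests whether a list moves 1 way on balance against no change and makes no comparison with other genes. Counts "over the list alone" use Benjamini-Hochberg adjustment within that list. Of the list members, 21 were not matched to a symbol and are not analysed here, Gapdh, Ep300, Pecam1, E2f1 and Nos2 among them. Genes are named by a rule: the 10 largest rises and 10 largest falls among genes with a symbol whose groups do not overlap and whose mean FPKM is at least 5 in the higher group, up to 4 changed members of each list, and 13 genes named for the question of the study. A gene named outside that rule is said to have been chosen after its values were seen.

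Library totals were 72.1, 80 and 79.2 M counts for DMSO replicates 1 to 3, and 77.2, 72.7 and 79 M for FSK replicates 1 to 3. TMM factors ran from 0.964 to 1.04. The biological coefficient of variation of the fit was 20.8%. Replicates differed by more than counting noise (chi-square per degree of freedom 30.8 to 56.7). The test was checked on simulated counts with these depths and dispersions, in which 200 of 14166 genes were changed. It recovered 43.3% of the genes changed 1.5-fold, 64.2% of those changed 2-fold and 83.3% of those changed 4-fold, and 11 of 138 calls (8%) were unchanged genes. The real comparison called 5576 genes, so its adjusted threshold sat at a larger unadjusted p. These recovery rates therefore do not carry over to it. The labels number the replicates but do not say that they are separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 3 libraries per group, the groups of a gene without any difference fail to overlap with a 10% chance.

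Other settings were limma on log2 FPKM with pseudocounts of 1, 0.1 and 5, with TMM or quantile normalisation and without a variance trend; no filter; a minimum FPKM of 5; a minimum fold change of 2; DESeq2 1.42.0 and its size factors; a replicate block; and leaving out each library. Robust dispersion, removal of a trend with transcript length, and removal of genes with a 0 and a count of at least 100 in the same group were added afterwards, as were the KEGG groups annotated in the table, of which 298 with 10 to 300 tested genes were used. Transcript length here is the length implied by a gene's count, FPKM and library total, as a median over libraries. It may differ from the annotated length. A planned test of miR-221/222 sites in 3' untranslated regions and a planned test of CRE motifs in promoters need sequence and were not run, and p-values computed by the authors are not analysed here.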

Results

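C6 glioma cells were compared after 24 h in forskolin (FSK) or DMSO, with 3 libraries of 72.1 to 80 M counts in each group and 17832 genes with at least 1 count. The first principal component held 49% of the variance and separated FSK from DMSO, against 14.1% and 12.9% for the next components. Spearman correlations were 0.990 to 0.992 within a group and 0.968 to 0.974 between groups. Mitochondrially encoded genes took 2.81, 2.75 and 3.03% of counts in DMSO and 3.59, 3.38 and 3.28% in FSK.

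Forskolin changed the RNA of a large part of the expressed genome, with similar numbers of rises and falls at the threshold used and more falls among larger changes. The 10 largest rises under the naming rule include 3 cytokine and 3 metalloproteinase genes, and the 10 largest falls include the matrix genes Mepe, Eln and Col15a1. These groupings are read from the named genes and were not tested for enrichment. Of 14166 tested genes, 2772 rose and 2804 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted), and 8590 did not pass. At least 1.5-fold, 1024 rose and 1408 fell. At least 2-fold, 488 rose and 604 fell, and at least 4-fold, 156 and 172. Limma on FPKM without further scaling gave 2262 rises and 3168 falls, so the balance depends on scaling. FSK and DMSO values did not overlap for 5526 of the 5576 changed genes and for 53% of all tested genes, where chance gives 10%.

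The largest rise under the naming rule was that of Tyrp1 (ENSRNOG00000029318; chr5:98387291-98406083), which encodes an enzyme of melanin synthesis: 0.459 ± 0.251 CPM in DMSO and 341.8 ± 18.7 in FSK (n = 3), a log2 fold change of 9.55 ± 0.30 (adjusted p = 5.91e-07). Fbln5, encoding an elastic-fibre protein, rose by 6.64 ± 0.44 (adjusted p = 2.03e-05; 7.57 without DMSO replicate 3). Gng14, a G-protein gamma subunit gene, rose by 5.60 ± 0.70 (adjusted p = 0.000547; 5.00 without DMSO replicate 3). Also among the 10 largest rises (log2 fold change ± SE, adjusted p) were the cytokine genes Il11 (5.58 ± 0.17, 5.24e-07), Il6 (5.03 ± 0.22, 2.7e-06) and Csf3 (4.73 ± 0.13, 3.23e-07). So were the metalloproteinase genes Mmp10 (5.56 ± 0.18, 6.89e-07), Mmp3 (5.28 ± 0.08, 1.8e-08) and Mmp13 (4.62 ± 0.37, 5.11e-05). Mmp3 reached 453.7 ± 7.47 CPM from 11.7 ± 1.06, and Csf3 135.7 ± 1.80 from 5.13 ± 0.885. Egfl8 rose by 4.69 ± 0.10 (adjusted p = 7.38e-08), but it overlaps Agpat1 on the opposite strand and LOC103689965, and its counts cannot be separated from theirs here. AABR07019383, chosen after its values were seen, is a processed transcript with 0 counts in every DMSO library and 34.1 CPM in FSK, at least 896-fold higher (adjusted p = 6.77e-07).

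The largest fall was that of Mepe (ENSRNOG00000002154; chr14:6782012-6793558), which encodes a phosphoglycoprotein of mineralised matrix: 470.6 ± 7.51 CPM in DMSO and 14.3 ± 0.921 in FSK (log2 fold change -5.04 ± 0.07, adjusted p = 1.28e-08). Eln, the elastin gene, went from 138.8 ± 14.2 to 4.46 ± 1.38 CPM (-4.96 ± 0.21, 2.18e-06), and Col15a1 fell by 3.62 ± 0.18 (4.46e-06). Brinp1 (-4.22 ± 0.24, 8.39e-06) and the potassium channel gene Kcng1 (-2.96 ± 0.21, 2.59e-05) fell, as did the integrin gene Itga4 (-2.78 ± 0.17, 1.15e-05) and the growth factor gene Igf1 (-3.03 ± 0.14, 3.86e-06). Genes tied to amino-acid, redox and other stress were also among the 10 largest falls: Chac1 (-3.20 ± 0.09, 4.09e-07), Txnip (-3.18 ± 0.25, 4.91e-05) and Nupr1 (-3.13 ± 0.26, 7e-05).

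**Figure D1:**
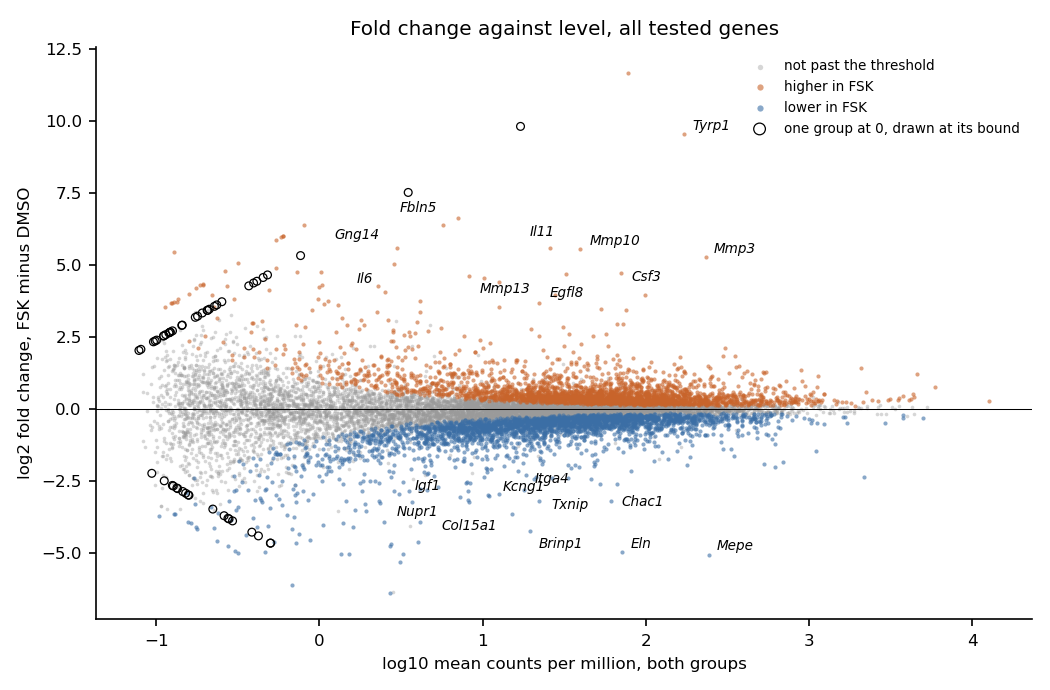
Log2 fold change (FSK minus DMSO) against log10 mean CPM for the 14166 tested genes, 1 point per gene: orange higher in FSK, blue lower, grey not past the threshold, open circles genes with a group at 0 drawn at their bound. Tyrp1 (9.55) and Mepe (-5.04) are the largest rise and fall under the naming rule.

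The astrocyte genes Gfap and S100b and the neuronal tubulin gene Tubb3 rose, and the progenitor gene Nes fell. Astrocyte and oligodendrocyte markers went both ways, with more rises than falls. Neuron markers as a list did not shift against the other genes. Gfap (ENSRNOG00000002919; chr10:90990762-90999506), the intermediate filament gene of astrocytes, rose 11-fold from 12.6 ± 0.414 to 138.7 ± 6.58 CPM (log2 fold change 3.46 ± 0.06, adjusted p = 5.15e-08). S100b rose by 1.84 ± 0.06 (5.91e-07), from 152.8 ± 9.69 to 545.8 ± 4.50 CPM. Tubb3 (ENSRNOG00000017209; chr19:56220755-56229813) rose by 1.24 ± 0.11 (9.22e-05) but stayed low, from 10.8 ± 0.937 to 25.6 ± 2.33 CPM. Nes fell by 0.90 ± 0.06 (2.72e-05), from 376.2 ± 10.9 to 201.0 ± 15.6 CPM.

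Of 14 astrocyte markers tested, 6 rose, 3 fell and 5 did not pass (6 and 3 over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 2.09e-07). With an estimated correlation the list had adjusted p = 0.0866, and over the other alternatives its median ran from 0.399 to 0.981. Beside Gfap and S100b, Fgfr3 rose (1.22 ± 0.09, 2.73e-05), whereas the glutamate transporter gene Slc1a3 fell by 1.38 ± 0.28 (0.00537). Of 11 oligodendrocyte markers, 6 rose, among them Cnp (1.03 ± 0.06, 9.4e-06) and Sox10 (0.82 ± 0.08, 0.000134), and 3 fell, with Cspg4 at -0.89 ± 0.07 (4.67e-05); the counts over the list alone were the same. This list's median was 0.39 (camera adjusted p = 0.0311), and it had adjusted p = 0.27 with an estimated correlation, 0.125 without DMSO replicate 3, and 0.00986 to 0.256 over the other alternatives; without DMSO replicate 1 its median was 0.65.

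Of 14 neuron markers, 3 rose and 6 fell (3 and 7 over the list alone), 5 did not pass, and the median was -0.26 (camera adjusted p = 0.223 against the other genes, fry adjusted p = 0.00419 against no change). The neuron median was -0.79 without DMSO replicate 2, -0.56 without DMSO replicate 3 and -0.49 without FSK replicate 2. Map2 fell by 1.24 ± 0.24 (0.00442), and the growth-cone gene Gap43 by 3.29 ± 0.42 (0.000594), with -3.89 without FSK replicate 2. Of 13 neural progenitor genes, 5 rose, 3 fell and 5 did not pass (6 and 4 over the list alone). Myc rose (1.25 ± 0.05, 2.28e-06), and Id4 (-1.36 ± 0.10, 4.16e-05) and Klf4 (-1.03 ± 0.06, 1.56e-05) fell. The progenitor median was 0.17 and the mean -0.03, and the list passed neither test (camera adjusted p = 0.684, fry 0.0959).

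**Figure D2:**
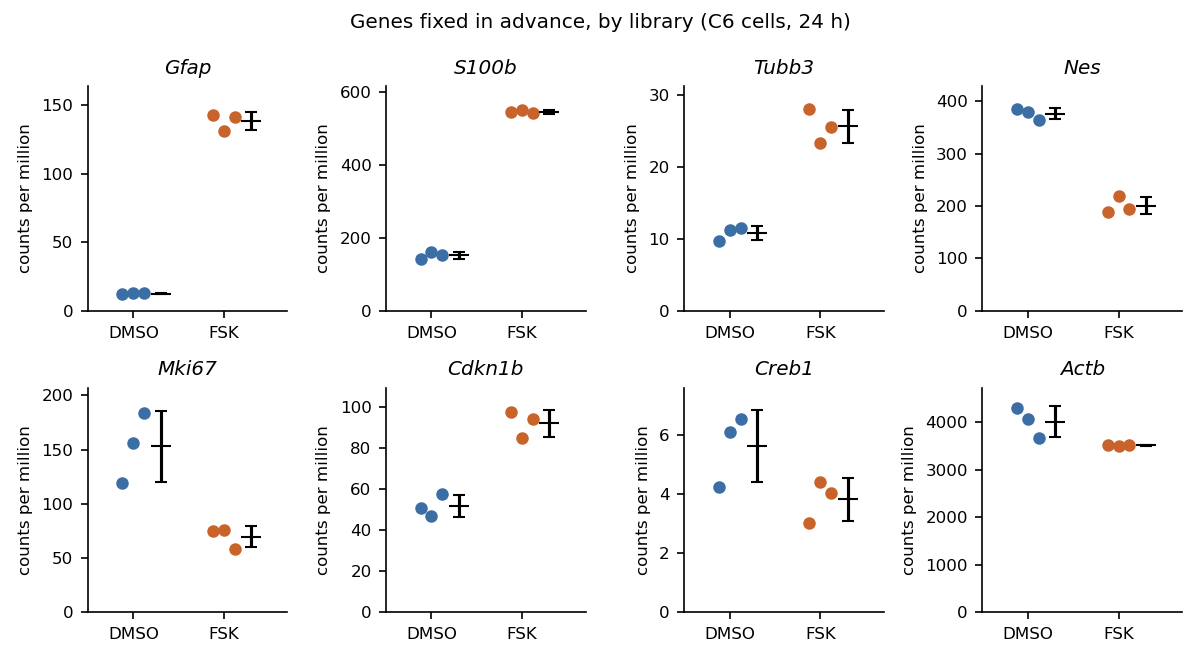
CPM of 8 genes named for the question of the study, 1 point per library, with the mean and SD of the 3 libraries as a bar. Gfap went from 12.6 to 138.7 CPM and Nes from 376.2 to 201.0, whereas Creb1 did not pass and Actb differed little.

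More CREB1 target genes rose than fell, and more genes of the cAMP and PKA pathway fell than rose. Most phosphodiesterases that degrade cAMP rose, Pde10a and Pde4b among them. The transcript of CREB1 itself did not pass. Of 26 CREB targets, 17 rose, 5 fell and 4 did not pass (17 and 5 over the list alone), with a median of 0.70, also with Pde10a at its bound (camera adjusted p = 1.07e-06). The list had adjusted p = 0.0866 with an estimated correlation, and its median ran from 0.229 to 0.798 over the other alternatives. Pde10a had 0 counts in the 3 DMSO libraries and 428, 595 and 534 in FSK, at least 184-fold higher (adjusted p = 1.62e-05). Fos rose by 2.87 ± 0.12 (2.24e-06), Pde4b by 2.21 ± 0.12 (5.9e-06) and Pde7b by 2.19 ± 0.22 (0.000185). Creb1 had 5.63 ± 1.22 CPM in DMSO and 3.82 ± 0.714 in FSK (log2 fold change -0.56 ± 0.22, adjusted p = 0.0768). Without DMSO replicate 1 it was -0.73 with adjusted p = 0.0311, with limma on FPKM 0.046, 0.0483 and 0.0441 (pseudocounts of 1, 0.1 and 5), and over all alternatives 0.0311 to 0.206.

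Of 12 phosphodiesterase genes, 7 rose, 1 fell and 4 did not pass (7 and 1 over the list alone), with a median of 0.39, also with Pde10a at its bound (camera adjusted p = 0.00232); the gene that fell was Pde2a (-1.80 ± 0.26, 0.00107). This list shares Pde10a, Pde4b and Pde7b with the CREB targets, and it had adjusted p = 0.215 with an estimated correlation. Of 26 cAMP and PKA pathway genes, 2 rose, 13 fell and 11 did not pass (2 and 13 over the list alone), with a median of -0.31 (camera adjusted p = 0.00566). The list had adjusted p = 0.215 with an estimated correlation and 0.0623 with a minimum FPKM of 5, the highest of its 0.00323 to 0.0623 over the other alternatives. With the length trend removed its median was -0.185 and 10 genes fell (adjusted p = 0.0141). Rapgef3, encoding the cAMP sensor EPAC1, fell by 2.31 ± 0.23 (0.000177), the PKA inhibitor gene Pkia by 1.33 ± 0.12 (9.39e-05) and the PKA anchor gene Akap12 by 1.23 ± 0.06 (4.69e-06). The larger KEGG cAMP signalling group, chosen after its values were seen, had 23 rises and 40 falls among 129 genes (camera adjusted p = 0.333).

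Nearly all G2/M genes and most G1/S genes on the lists fell. The CDK inhibitor gene Cdkn1b rose. Of 39 G2/M genes, 38 fell and none rose; Ube2c did not pass (-0.12; adjusted p = 0.099), and all 39 fell over the list alone. Their median was -0.59 (camera adjusted p = 8.1e-11), with adjusted p = 0.127 with an estimated correlation. Kif20b (-1.28 ± 0.21, 0.00226), Cenpf (-1.28 ± 0.26, 0.00618) and Ckap2l (-1.04 ± 0.15, 0.00123) fell most with Mki67, which went from 153.1 ± 32.5 to 69.8 ± 9.87 CPM (-1.13 ± 0.16, 0.00104). Of 39 G1/S genes, 1 rose, 25 fell and 13 did not pass (1 and 26 over the list alone), with a median of -0.33 (camera adjusted p = 0.000436). The G1/S list had adjusted p = 0.215 with an estimated correlation. The DNA polymerase gene Pola1 (-1.10 ± 0.15, 0.000832), Blm (-0.97 ± 0.11, 0.000277), Usp1 (-0.95 ± 0.12, 0.000465) and Dscc1 (-0.89 ± 0.17, 0.00486) fell. Among KEGG groups chosen after their values were seen, cell cycle had 17 rises and 46 falls among 117 genes (camera adjusted p = 0.0912), DNA replication 2 and 21 of 36 (0.0228), homologous recombination 1 and 19 of 38 (0.0311) and oocyte meiosis 9 and 39 of 90 (0.034). Each of these 4 groups had adjusted p = 0.562 with an estimated correlation. With the transcript length trend removed they had 0.15, 0.0325, 0.0497 and 0.054, in the same order.

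Cdkn1b, encoding p27, rose by 0.83 ± 0.09 (adjusted p = 0.000235), from 51.7 ± 5.37 to 92.2 ± 6.64 CPM. The list of CDK inhibitor and D cyclin genes also holds Cdk6 and Rb1. Of its 9 tested genes, 2 rose, 5 fell and 2 did not pass (3 and 5 over the list alone). Their median was -0.49 (camera adjusted p = 0.284 against the other genes, fry 0.000893 against no change). Cdk6 (-1.21 ± 0.11, 0.000126) and Rb1 (-0.88 ± 0.16, 0.00368) fell. The D cyclin gene Ccnd2 fell by 0.71 ± 0.24 (0.048), with overlapping groups and adjusted p = 0.0128 to 0.148 over its alternatives. Cdkn1c had 0, 0 and 12 counts in DMSO and 8, 3 and 0 in FSK, too few to test.

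Reported targets of miR-221 and miR-222 did not shift in either direction. The microRNA hairpin genes themselves had almost no counts. Of 35 reported targets, 7 rose, 14 fell and 14 did not pass (9 and 16 over the list alone), with a median of -0.14 (camera adjusted p = 0.571, fry 0.189). Among those that changed, the chemokine gene Cx3cl1 rose by 3.77 ± 0.27 (3.08e-05) and Socs3 by 1.14 ± 0.08 (2.7e-05), Rb1 fell, and Cdkn1b rose. Kit fell by 1.17 ± 0.37 (adjusted p = 0.0357), from 2.84 ± 1.10 to 1.26 ± 0.375 CPM, with overlapping groups. Its adjusted p was 0.0986 to 0.11 without DMSO replicate 1, DMSO replicate 3, FSK replicate 1 or FSK replicate 3, and 0.00889 to 0.11 over all alternatives. Mir221 (chrX:3684480-3684588) had 2, 5 and 4 counts in DMSO and 3, 0 and 1 in FSK, and Mir222 had 0 in all 6 libraries. Neither hairpin gene passed the filter, and mature microRNAs are not analysed here.

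More matrix protease and inhibitor genes rose than fell, and more extracellular matrix genes fell than rose. Some of the strongest changes sat in clusters of related neighbouring genes. Of 23 protease and inhibitor genes, 13 rose, 5 fell and 5 did not pass (14 and 7 over the list alone), with a median of 0.29 (camera adjusted p = 4.08e-10). That list had adjusted p = 0.0866 with an estimated correlation. Mmp2 rose by 2.81 ± 0.20 (2.7e-05). Mmp13, Mmp3 and Mmp10 lie together on chromosome 8, from 5522739 to 5742243, while Dcun1d5 beside them did not pass (-0.01, 0.941) and Dync2h1 fell by 0.84 (0.0155; 0.0599 without FSK replicate 3). Whether the rise took in the rest of the family there cannot be told. Mmp12, Mmp1b and Mmp1 between them, and Mmp8, Mmp27, Mmp20 and Mmp7 beyond, had at most 17 counts in any library and were not tested. Mmp7 had 0 counts in every DMSO library and 6, 4 and 17 in FSK, whereas Mmp1b, Mmp8 and Mmp27 had 0 in all 6 libraries. Of 34 extracellular matrix genes, 8 rose, 17 fell and 9 did not pass (8 and 18 over the list alone), with a median of -0.20 (camera adjusted p = 2.53e-10). The matrix list had adjusted p = 0.238 with an estimated correlation, and its median was -0.12 without FSK replicate 1 and -0.35 without FSK replicate 2. With the transcript length trend removed its median was -0.04, with 10 rises and 15 falls (adjusted p = 1.06e-06, 5.44e-12 to 0.0287 over all alternatives with the preset correlation). Within this list, after Eln, the aggrecan gene Acan fell most (-3.90 ± 0.23, 1.12e-05), then Spp1, the osteopontin gene (-2.33 ± 0.10, 2.4e-06), whereas Col18a1 rose by 2.12 ± 0.07 (6.97e-07). Spp1 and Mepe are neighbours of Ibsp, which also encodes a phosphoprotein of bone matrix and fell by 1.42 ± 0.11 (3.89e-05), in the interval chr14:6673686-6813945. The fall was not confined to these genes: Pkd2 beside Spp1 fell by 0.75 ± 0.06 (3.49e-05), while Nudt9 (-0.12, 0.103) and Hsd17b11 (-0.07, 0.399) did not pass. Abcg3l1, further along, rose by 0.50 ± 0.14 (0.0204), with adjusted p = 0.0619, 0.077, 0.0538 and 0.0642 without DMSO replicate 1, DMSO replicate 2, FSK replicate 1 and FSK replicate 2 (0.00922 to 0.077 over the 6 libraries left out). Ibsp and the flanking genes were chosen after their values were seen.

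**Figure D3:**
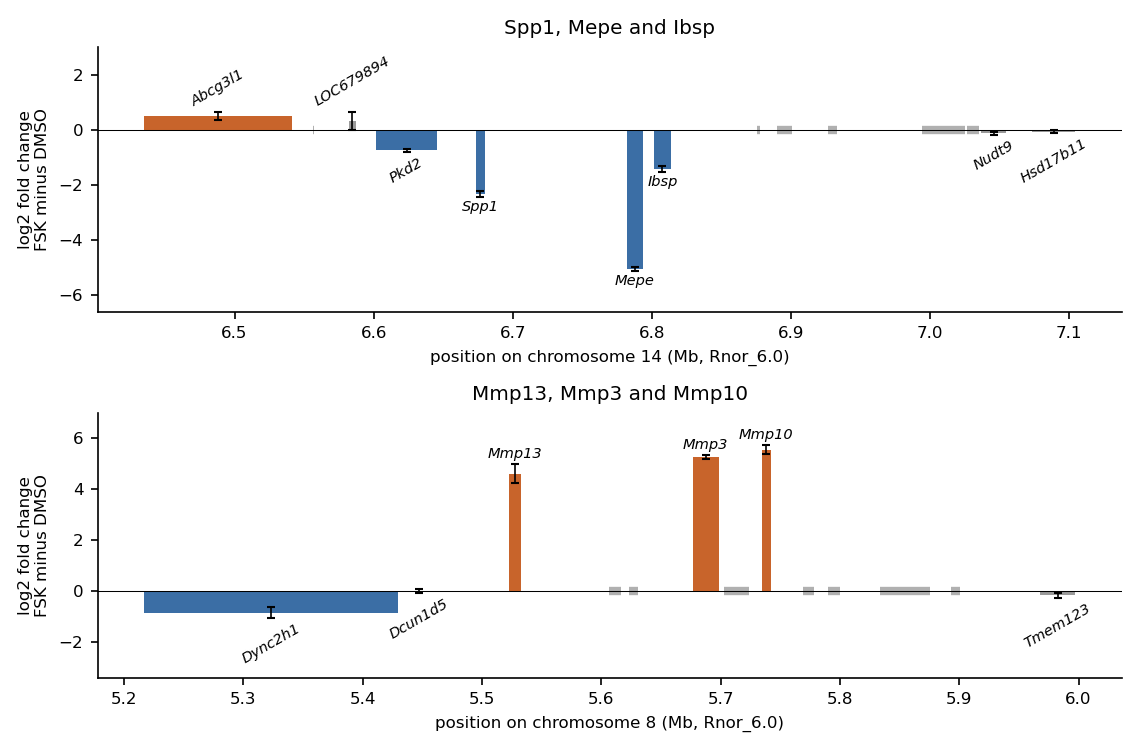
Log2 fold change (FSK minus DMSO, bar ± SE) drawn over gene positions in megabases at the Spp1, Mepe and Ibsp locus and at the Mmp13, Mmp3 and Mmp10 locus, orange higher in FSK, blue lower, grey boxes untested. Mepe (-5.04), Mmp10 (5.56) and Pkd2 (-0.75) changed, while Nudt9 (-0.12) and Dcun1d5 (-0.01) did not pass.

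More cytokine and NF-kB target genes rose than fell, and growth factor genes changed in both directions. ERK feedback genes also went both ways, with more rises than falls. Of 24 NF-kB target and cytokine genes, 10 rose, 3 fell and 11 did not pass (10 and 3 over the list alone), with a median of 0.19 (camera adjusted p = 0.00322) and adjusted p = 0.127 with an estimated correlation (median 0.30 without DMSO replicate 2). Il11, Il6 and Cx3cl1 led the rises, and the adhesion gene Vcam1 fell by 2.77 ± 0.27 (0.000134). Of 2 KEGG groups chosen after their values were seen, NF-kappa B signalling had 15 rises and 9 falls among 68 genes (camera adjusted p = 0.72). Cytokine-cytokine receptor interaction had 37 and 18 of 112 (camera adjusted p = 0.00178, 0.562 with an estimated correlation). Of 19 ERK feedback genes, 9 rose, 5 fell and 5 did not pass (10 and 6 over the list alone), with a median of 0.15 (camera adjusted p = 0.0311). The ERK list had adjusted p = 0.442 with an estimated correlation, 0.0524 without DMSO replicate 1, 0.17 without DMSO replicate 3, and 0.0136 to 0.362 over the other alternatives. Ier3 (1.30 ± 0.05, 1.39e-06), Dusp6 (0.82 ± 0.04, 7.02e-06) and Dusp5 (0.79 ± 0.10, 0.000608) rose. Of 25 growth factor genes, 8 rose, 7 fell and 10 did not pass, also over the list alone 8 and 7 (median 0.29, camera adjusted p = 0.284, fry 0.00857): Fgf7 (1.64 ± 0.10, 1.26e-05) and Hbegf (1.41 ± 0.07, 6.2e-06) rose against the fall of Igf1. Of 20 interferon genes, 5 rose, 6 fell and 9 did not pass (5 and 7 over the list alone; median -0.27, camera adjusted p = 0.684, fry 0.165), with Mx2 down by 2.15 ± 0.46 (0.00689).

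More unfolded-protein, integrated stress response and clock genes fell than rose. Heat shock genes had more rises than falls, but their list did not shift against the other genes. Ribosomal protein and cholesterol synthesis genes had more rises than falls, by small amounts. Of 27 unfolded-protein and integrated stress response genes, 2 rose, 15 fell and 10 did not pass (2 and 18 over the list alone), with a median of -0.31 (camera adjusted p = 3.46e-08) and adjusted p = 0.127 with an estimated correlation. After Chac1, the largest falls were those of Trib3 (-2.37 ± 0.17, 3.43e-05), the asparagine synthetase gene Asns (-1.45 ± 0.13, 0.00011) and Sesn2 (-1.20 ± 0.08, 1.89e-05). KEGG protein processing in endoplasmic reticulum, chosen after its values were seen, had 28 rises and 48 falls among 152 genes (camera adjusted p = 0.471). Of 12 heat shock genes, 4 rose, 1 fell and 7 did not pass, with the same 4 and 1 over the list alone (median 0.19, camera adjusted p = 0.141, fry 0.00857), and Hsph1 rose by 0.89 ± 0.08 (0.000102). Of 15 p53 targets, 5 rose, 4 fell and 6 did not pass, 5 and 4 over the list alone (median 0.10, camera adjusted p = 0.365, fry 0.00129), with Gdf15 up by 1.45 ± 0.15 (0.0002). The KEGG p53 signalling group, chosen after its values were seen, had 9 rises and 25 falls among 63 genes (camera adjusted p = 0.0419). It had 0.562 with an estimated correlation and 0.054 with the transcript length trend removed. Of 18 clock genes, 1 rose, 8 fell and 9 did not pass (1 and 8 over the list alone; median -0.37, camera adjusted p = 0.0363). The clock list had adjusted p = 0.357 with an estimated correlation, 0.0622 without FSK replicate 1, 0.0651 with the transcript length trend removed, and 0.0156 to 0.0923 over the other alternatives. Ciart fell by 1.10 ± 0.09 (6.06e-05), Per2 by 0.70 ± 0.10 (0.00109) and Per3 by 0.63 ± 0.13 (0.00533). The KEGG circadian rhythm group, chosen after its values were seen, had 6 rises and 8 falls among 28 genes (camera adjusted p = 0.655).

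Of 36 ribosomal protein genes, 26 rose, none fell and 10 did not pass (29 rose over the list alone), with a median of 0.23 (camera adjusted p = 0.000327) and adjusted p = 0.476 with an estimated correlation. Rplp1 rose by 0.45 ± 0.05 (0.000348) and Rpl35 by 0.31 ± 0.05 (0.00217). Of 23 cholesterol synthesis genes, 13 rose, 2 fell and 8 did not pass (14 and 2 over the list alone), with a median of 0.24 (camera adjusted p = 0.00652) and adjusted p = 0.442 with an estimated correlation. Hmgcs1 rose by 0.55 ± 0.06 (0.000313) and Nsdhl by 0.49 ± 0.06 (0.000505). The other metabolic lists did not shift against the other genes in camera; against no change, fry gave adjusted p = 0.0244 for fatty acid, 0.189 for glycolysis, 0.0899 for oxidative phosphorylation and 0.0015 for hypoxia genes. Of 15 fatty acid genes, 7 rose and 3 fell, also over the list alone (median 0.14, camera adjusted p = 0.389), Fasn by 0.53 ± 0.08 (0.00111). Of 19 glycolysis genes, 3 rose and 5 fell, also over the list alone (median 0.07, 0.405), with Ldha up by 1.22 ± 0.05 (2.24e-06) and Slc16a1 down by 0.64 ± 0.07 (0.000238). Of 34 oxidative phosphorylation genes, 8 rose and none fell (5 over the list alone; median 0.08, 0.306), Cox4i1 by 0.26 ± 0.05 (0.00588). The larger KEGG group of oxidative phosphorylation, chosen after its values were seen, had 56 rises and 4 falls among 128 genes (camera adjusted p = 0.00367, 0.71 with an estimated correlation and 0.161 with the transcript length trend removed). Of 16 hypoxia genes, 5 rose and 5 fell, also over the list alone (median 0.05, 0.39), Vegfa by 0.78 ± 0.09 (0.000452).

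Lysosomal genes, a KEGG group chosen after the values were seen, had more rises than falls: of 104 tested, 51 rose and 9 fell, with a median of 0.30 (camera adjusted p = 6.3e-07 over 298 groups). The group had adjusted p = 0.562 with an estimated correlation. The cathepsin gene Ctsd rose by 0.97 ± 0.04 (2.4e-06), the membrane protein gene Lamp1 by 0.82 ± 0.04 (4.95e-06) and the proton pump subunit genes Atp6v1b2 by 0.81 ± 0.06 (3.46e-05) and Atp6v1h by 0.79 ± 0.06 (5.45e-05), whereas the lipase gene Lipa fell by 0.83 ± 0.05 (1.51e-05). Gpnmb, a gene of lysosomes and pigment organelles, rose by 1.81 ± 0.07 (1.22e-06). The transcripts of the lysosomal regulators Tfeb (-0.32, 0.0813) and Tfe3 (-0.06, 0.65) did not pass, but Tfeb did without DMSO replicate 3 (0.0209) and without FSK replicate 3 (0.0481). The genes named in this group were chosen after their values were seen.

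The next lists did not shift against the other genes in camera, but several did against no change in fry. Its adjusted p was 0.00857 for YAP, 0.00915 for SRF and actin, 0.00434 for Wnt, 0.00129 for TGF-beta and BMP, 0.00957 for secretory granule and 0.0844 for glutamate and GABA genes. Of 22 YAP targets, 3 rose, 9 fell and 10 did not pass (4 and 11 over the list alone; median -0.33, camera adjusted p = 0.0886), with Arhgef17 down by 1.31 ± 0.09 (3.04e-05) and Ccn2 by 0.81 ± 0.09 (0.000253). Of 20 SRF and actin genes, 4 rose and 7 fell (5 and 7 over the list alone; median -0.20, 0.39), Lmod1 by 2.35 ± 0.24 (0.000175). Of 20 Wnt genes, 9 rose and 3 fell (9 and 4 over the list alone, median 0.26, 0.088), with Wnt4 up by 1.63 ± 0.11 (1.89e-05). Also among its largest changes, Wif1 rose by 1.34 ± 0.15 (0.000346) and Dkk3 by 1.14 ± 0.23 (0.00567). Sfrp2 rose by 2.08 ± 0.53 (0.0157, with 0.00165 to 0.0516 over its alternatives). Of 21 TGF-beta and BMP genes, 7 rose and 2 fell, also over the list alone (median 0.10, 0.088), with Bmp2 up by 1.43 ± 0.05 (6.97e-07). Of 8 secretory granule genes, 2 rose and 5 fell, also over the list alone (median -0.54, 0.136): Vgf rose by 1.86 ± 0.25 (0.000708) and the enkephalin gene Penk fell by 1.61 ± 0.04 (3.23e-07). Of 16 glutamate and GABA genes, 2 rose and 5 fell, also over the list alone (median -0.09, 0.39), Gria4 by 1.66 ± 0.25 (0.00126). Actb, a common reference gene, fell by 0.19 ± 0.06 (adjusted p = 0.034), from 4011 ± 324.8 to 3510 ± 7.78 CPM. Its adjusted p was 0.0501, 0.103, 0.0776, 0.0931 and 0.0923 without DMSO replicate 1, DMSO replicate 2 and FSK replicates 1, 2 and 3, and 0.00121 to 0.103 over all alternatives.

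Microglia, endothelial and fibroblast markers did not shift against the other genes in camera, and against no change fry gave adjusted p = 0.0531, 0.00771 and 0.00915. Of 8 microglia markers, Cd68 rose (3.11 ± 0.23, 3.74e-05), Tmem119 fell and 6 did not pass, also over the list alone (median 1.31, camera adjusted p = 0.226). The microglia list had a median of 3.68 and adjusted p = 0.0157 without DMSO replicate 3 (0.0157 to 0.276 over its alternatives). The fall of Tmem119 (-0.29, 0.0175) had adjusted p = 0.0547, 0.0673, 0.0506 and 0.0637 without DMSO replicate 1, DMSO replicate 2, FSK replicate 1 and FSK replicate 2, and 0.0016 to 0.0673 over its alternatives. Of 7 endothelial markers, 2 rose and 3 fell, also over the list alone (median -0.26, 0.39): Esam rose by 2.29 ± 0.45 (0.00475; 2.90 without DMSO replicate 2) and Flt1 fell by 0.79 ± 0.06 (4.32e-05). The endothelial median ran from -0.828 to -0.131 over its alternatives. Of 10 fibroblast markers, 1 rose and 3 fell, also over the list alone (median -0.39, 0.0579), with Col3a1 down by 1.72 ± 0.06 (6.97e-07) and Col1a1 by 0.54 ± 0.12 (0.00932). That list had adjusted p = 0.0423 without DMSO replicate 1 and 0.0325 without FSK replicate 1 (0.0325 to 0.352 over its alternatives). Of the 36 lists, 15 shifted against the other genes with the preset correlation and 0 with an estimated correlation in camera, where the lowest adjusted p was 0.0866 and 7 lists had an unadjusted p under 0.05. Against no change, 29 of the 36 passed in fry, which does not set a list against the 5576 of 14166 tested genes that changed.

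**Figure D4:**
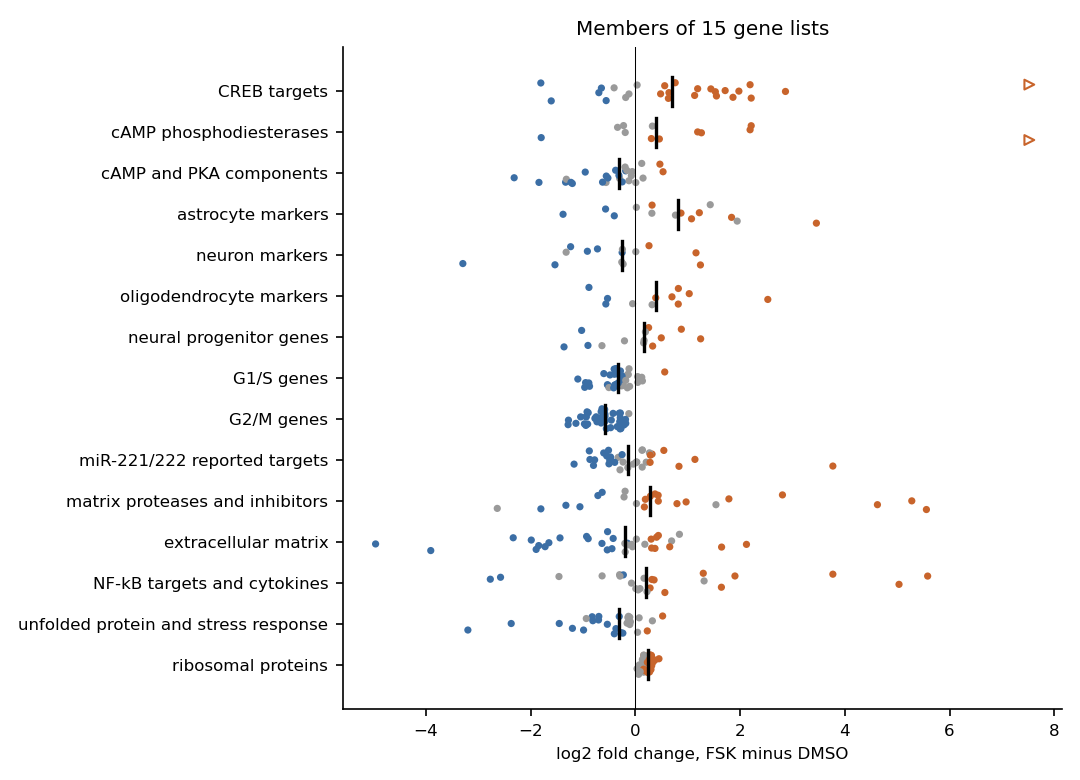
Log2 fold change (FSK minus DMSO) of the tested members of 15 gene lists, 1 point per gene, orange higher in FSK, blue lower, grey not past the threshold, a black line for the list median and an open triangle for Pde10a at its bound. G2/M genes (median -0.59) lie almost all below 0, and CREB targets (0.70) and astrocyte markers (0.82) mostly above it.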

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

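Robust dispersion, the length trend and the removal of genes with a 0 beside a high count were chosen after the results were seen; the other alternatives were planned. Apart from a minimum fold change, 4245 to 6227 genes changed against 5576, and no called list or named gene changed direction. Leaving out 1 library at a time gave 4245 to 5405 changed genes (2169 to 2667 higher, 2076 to 2738 lower) and 14 to 15 shifted lists. A fold change of at least 2 left 1092 genes, 488 higher and 604 lower; this follows from its construction. Limma on log2 FPKM gave 5430 genes with a pseudocount of 1 (41.7% higher), 5398 with 0.1, 5441 with 5, 5335 with TMM, 5362 with quantile normalisation and 5266 without a trend. No filter gave 5211 genes, a minimum FPKM of 5 gave 4400 and 8 lists, DESeq2 size factors 5576 and DESeq2 6227. A replicate block gave 4325 genes (2160 higher, 2165 lower) and 15 lists; replicates of the same number were no more alike than others (residual correlations -0.041, 0.018 and -0.035, against -0.022 to 0.056). Robust dispersion gave 5726 genes, removal of the length trend 5461, and removal of genes with a 0 beside a high count 5716. An estimated correlation left 0 of 15 lists, with a lowest adjusted p of 0.0866. The estimate was 0.0134 for CREB targets, -0.0496 for astrocyte markers and -0.0197 for NF-kB and cytokine genes, near or below the preset 0.01. For these lists the loss is therefore no sign of a high correlation. Other estimates were higher, such as 0.521 for ribosomal proteins. Of the 15, 8 passed every other alternative in which they were tested; the phosphodiesterase list, among the 8, had too few genes at a minimum FPKM of 5. With quantile normalisation, the cholesterol synthesis (adjusted p = 0.0575, range 0.00246 to 0.0723), NF-kB and cytokine (0.0894, range 0.00161 to 0.0894) and ribosomal protein (0.0773, range 1.42e-05 to 0.0773) lists did not pass. The Wnt list passed without a filter (0.0496, range 0.0496 to 0.211) and the TGF-beta and BMP list with the length trend removed (0.0298, range 0.0298 to 0.206). For the results that moved, the cause was not tested. Of 147 changed named genes, 125 passed every alternative in which they were tested, and genes of low FPKM were not tested in all. The 3' untranslated region site test, the CRE motif test and the authors' p-values were not run.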

Other observations

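The transcript length, neighbouring gene and zero-count patterns were noticed in these data and then tested on the same data, and the tests of few reads, of opposite-direction neighbours, of the ATF4 part, of pigment genes, of cilium genes and of KEGG groups were chosen after the results were seen. Of the 10 splits of the 6 libraries 3 against 3, 1, the real split, gave as many as its 5576 changed genes, and the highest other gave 1; 10 splits are too few for a share under 0.05.

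Longer transcripts tended to fall and shorter ones to rise, with length implied by counts and FPKM rather than annotated. The median log2 fold change went from 0.15 in the shortest length decile (median 617 bases) to -0.23 in the longest (6739 bases), with a Spearman correlation of -0.189 over 12046 genes. RNA integrity or library preparation that differed between groups could give such a slope, as could a response of long genes to forskolin, and replicates also differ, since against the DMSO mean DMSO replicate 1 went from 0.06 to -0.093 and DMSO replicate 3 from -0.052 to 0.073 over the same deciles. With the trend removed, the G2/M median was -0.568 (adjusted p = 7.03e-11) and the G1/S median -0.294 (0.000817), so length alone may not account for their fall, while the ribosomal protein median was 0.139 (0.0298) and that rise may be partly the trend. The KEGG ribosome and oxidative phosphorylation groups, with camera adjusted p = 0.00178 and 0.00367, had 0.232 and 0.161 with the trend removed. With an estimated correlation they had 0.749 and 0.71.

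Some genes had a 0 in 1 library and at least 100 counts in another of the same group. Of 89 such genes, only LOC103689931 was called (0.00849), with 18977, 15626 and 0 counts in FSK. Reads assigned to an overlapping or similar gene in some libraries could give this, and sampling of few reads was weighed against it. Such genes more often overlapped another gene or shared its description (45 of 89, 50.6%, against 28.2% of other tested genes, odds ratio 2.6, 95% interval 1.67 to 4.04, Fisher exact test p = 9.43e-06). Assignment between copies would give this. However, 62.9% of these genes had a LOC or other placeholder symbol, against 13.3% of other tested genes. The odds ratio was not computed within that class, so it does not separate shared reads from the kind of annotation. Selection sets a floor under their median count of 467.5 in the libraries above 0, but a 0 beside 13820 and 16049 counts, as for Selenbp1 in DMSO, is not a draw of few reads.

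Changed genes lay beside others that changed the same way more often than in shuffled positions, which may point to regional control. Pairs were left out if they overlapped or shared a description, a KEGG orthology number or the opening letters of the symbol. Of the 12694 adjacent pairs left, 83 changed at least 2-fold in the same direction. In 10000 shuffles the mean was 38.1 (27 to 50), with permutation test p = 1e-04, the smallest possible. Reads shared by genes that overlap or are alike by this rule may therefore not be the cause. Related genes that are unlike by this rule were kept. Pairs in opposite directions numbered 20 against 37.2 (26 to 49), fewer than by shuffling, which a clustering of responsive genes whatever their direction would not give. Shared regulation of a region and reads running on from a neighbour remain untested. Reads spanning annotated gene ends at the Pctp, Tmem100 and Mmd run would tell these apart.

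Within the stress list, the ATF4 part fell (median -0.96, 7 down and 1 up of 10, camera adjusted p = 4.57e-11). The endoplasmic reticulum part, of chaperone genes and also Xbp1, Herpud1, Edem1 and Sel1l, fell less (-0.16, 8 down and 1 up of 17, 0.0145). Its largest falls were those of Edem1 (-0.81) and Herpud1 (-0.70). Of the chaperone genes, Hsp90b1 fell (-0.53, 0.00153) and Hspa5 did not pass (0.04, 0.528). Both parts had adjusted p = 0.0948 with an estimated correlation. The difference of their medians was -0.8 (permutation test p = 0.00048, 100000 permutations). But the parts were drawn up after the largest falls had been seen. This permutation p is therefore no test of a mechanism, and the camera values of the parts are no independent test of their fall. A wider rise of pigment genes with Tyrp1 was not seen among those tested: 10 others had a median of -0.28, with 2 up, Pmel by 0.89 ± 0.06 (2.69e-05) among them, and 1 down. Tyr, Mlana, Oca2, Slc45a2 and Gpr143 did not pass the filter, and Mitf (-0.47 ± 0.60) and Ednrb (-0.68 ± 1.06) were imprecise. Gpnmb, which rose by 1.81, was not on this list. Motile cilium genes had a median of -0.605 (adjusted p = 0.0993, 24 tested), which leaves open whether they fell.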
